A study of Mus musculus with 6 samples.

How the data were processed

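The series holds RNA-seq of NIH3T3, an immortalised line of mouse embryo fibroblasts, carrying a radiation injury per the labels. Cells treated with plasma-derived exosomes, small membrane vesicles shed by cells, were set against cells given phosphate-buffered saline (PBS), each at the 72 h time point. Groups and replicate numbers were taken from the sample titles, with 3 libraries in each of 2 groups. The labels give no radiation dose, no species or preparation of the plasma, and no statement that the 3 libraries of a group came from separate cultures. P-values of single genes therefore measure the spread between these libraries, which may be technical. Those of annotated terms and of gene lists tested at a preset correlation, both described below, compare genes with other genes instead. An unirradiated group was not analysed here.

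RNA was isolated with the mirVana kit, libraries were made with the TruSeq Stranded mRNA kit and sequenced as paired ends on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name Trimmomatic, HISAT2, Bowtie2, Cufflinks, StringTie, HTSeq, SAMtools and DESeq and the mm9 genome build, without versions, order or roles. Whether reads were counted by strand is not given in the sources used here, so values of genes that overlap another gene or an antisense transcript are uncertain. The reference annotation at hand was for another build, so it served for gene names and transcript lengths and no coordinates are given.

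The deposited table holds 21878 genes with Entrez identifiers, of which 6374 were listed at 0 in all 6 libraries. Per library the authors deposited expression values that are read here as FPKM (fragments scaled to transcript length and to the mapped fragments of the library). The column headers say only expression, and FPKM was inferred from Cufflinks in the processing notes, from the unequal column sums and from the relation to length: the authors' mean normalized count per unit of expression rose with transcript length (Spearman 0.77 across 8958 genes with a mean count above 200). Library columns were matched to samples through the sample numbers in the labels, and 0 pairs of libraries held identical values. The same table holds the authors' own comparison, namely a normalized count signal as the mean of each group, a linear fold change (ratio) of exosomes over PBS, and the p-value and adjusted p-value of DESeq, per the file headers. The deposited column of log2 fold changes was not used because part of its cells held spreadsheet error text. In 27 rows the gene name had been turned into a date by a spreadsheet, and all 27 were repaired through their Entrez identifiers.

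Counts per library were not among the columns, so depth was worked out from the authors' deposited group means of normalized counts. Among genes with a mean under 3, the deposited means were sums of whole multiples of 3 steps, 1 for each library, in 100% of 2362 genes for PBS and 100% of 2441 genes for exosomes (tolerance 2e-05). The steps gave size factors of 0.988, 0.973 and 0.923 for PBS and 0.971, 1.112 and 1.054 for exosomes. With the deposited totals these correspond to an estimated 20100000, 19800000 and 18800000 counted reads in PBS replicates 1 to 3 and 19200000, 22000000 and 20900000 in exosome replicates 1 to 3. The individual counts of a library could not be separated from the group means, so no count model was fitted. The analysis fixed before the data were examined foresaw a test on counts and, where a table held only FPKM, the test used here.

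Genes with at least 1 FPKM in 3 or more of the 6 libraries were tested on log2(FPKM + 1), with a pseudocount of 1, by limma 3.58.1 in R 4.3.3 (moderated variances with a trend on abundance and robust estimation, group as the only term, two-sided). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called raised or lowered. A fold change on this scale understates the change of genes with low values. Changes are exosomes over PBS, and errors are SD for FPKM and standard errors (SE) for log2 changes. On simulated libraries with the abundance and spread of these, the test recovered 38.8% of genes changed by 0.25 on the log2 scale, 82.4% at 0.5, 99.6% at 1 and 100% at 2, and called 0.1% of unchanged genes, over 5 draws of 10274 genes with 200 changed in each. The changed genes were drawn only from those with a mean log2(FPKM + 1) of at least 2.

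Fixed before the data were examined were 29 gene lists covering ferroptosis, proliferation, the radiation response, fibroblast and wound functions, immune signalling, stress and metabolism, RNA composition and the other cell types whose RNA plasma vesicles or a mixed culture could bring. Lists with at least 5 tested genes were tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. In 20 simulated draws without any change camera called 0 lists, and it called a list shifted by 0.3 in 20 of 20 draws. Genes were drawn independently there, so these draws cannot show how often camera falsely calls lists of correlated genes. An estimated correlation and fry, which asks whether the genes of a list move without comparing them with other genes, were alternatives. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries and not from the genes, which by itself raises p. A call lost in that setting therefore need not reflect correlation between the genes of the list. The 15 transcripts of the mitochondrial genome list had no row in the table used here.

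Genes named in the text follow a rule fixed in advance. It takes the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap and whose higher mean is at least 1 FPKM, leaving out predicted gene models. It further takes the 3 members of smallest p in each list whose test passes and in the ferroptosis and proliferation lists, the most abundant marker of each other cell type, and 19 genes named whatever their result. Members named beyond these, as examples or because they moved against their list, were chosen after their values were seen. A gene that the rule takes in some lists is not reported here by name.

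Alternatives planned in advance and applied were a pseudocount of 0.1, no filter on low values, the replicate number as a block, each library left out in turn, a minimum log2 change of 1, and the set tests above. Alternatives chosen after seeing the data were median-of-ratios and upper quartile scaling of the FPKM, a filter of at least 5 FPKM, and limma's treat against a log2 change of 0.5. Enrichment of the KEGG and GO terms in the deposited table (one-sided hypergeometric tests, terms of 10 to 300 tested genes, annotated tested genes as background) was also added afterwards. Further calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and plots matplotlib 3.10.9.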

Results

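RNA-seq libraries were made from irradiated NIH3T3 mouse fibroblasts, 3 from cells treated with plasma-derived exosomes and 3 from cells given PBS, at 72 h. The series title names proliferation and ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, as the processes of interest in the healing of irradiated wounds. The libraries held an estimated 18800000 to 22000000 counted reads, and between 10080 and 10271 genes reached 1 FPKM in each. The 10 most abundant genes took 7.7% to 8.2% of the summed FPKM. Values below are mean FPKM ± SD (n = 3 libraries per group) and log2 changes of exosomes over PBS ± SE.

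Exosome-treated and PBS-treated cells differed widely and mostly by small amounts. Most tested immediate early, glycolytic and antioxidant response genes fell with exosomes, while most matrix and interferon response genes rose. With an estimated correlation the set test called the immediate early and glycolytic lists but not the antioxidant (adjusted p = 0.0575), matrix (0.226) and interferon (0.224) lists. That setting also has far fewer degrees of freedom, so a lost call need not reflect correlation between genes. Of 10274 genes tested, 2612 were raised and 1889 lowered (limma, adjusted p under 0.05), which is 43.8% of them, and the median absolute log2 change of these 4501 genes was 0.29. Changes of at least 2-fold were found in 41 raised and 75 lowered genes on the log2(FPKM + 1) scale, which shrinks low genes. Among the calls in the authors' deposited table they were found in 209 raised and 190 lowered genes. That table gives an adjusted p for 15844 genes, including genes that the filter here left out, so the counts come from unlike sets of genes. The 3 exosome values lay wholly on 1 side of the 3 PBS values in 55.6% of genes, against 10% by chance. The first principal component held 78.2% of the variance and separated the groups, with exosome libraries at 14.5 to 15.5 and PBS libraries at −18 to −11.2. Correlations across genes were 0.9944 to 0.997 within groups (6 pairs) and 0.9767 to 0.9852 between them (9 pairs). The authors' deposited table, from counts, lists 4106 genes at an adjusted p under 0.05, 1966 raised and 2140 lowered, so that raised genes made up a smaller share there than in the FPKM test. Of the genes called in the authors' deposited table, 3464 were also called here, all 3464 in the same direction. Log2 changes on the log2(FPKM + 1) scale correlated with the log2 folds of the authors' deposited table at 0.965 across genes, which are not independent replicates.

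The largest rises were in Fibin, a secreted factor first described in fin bud development, at 12.1 ± 0.369 FPKM with exosomes and 2.25 ± 0.364 with PBS (log2 change 2.01 ± 0.08, limma adjusted p = 5.42e-07), and in Car6, a secreted carbonic anhydrase, at 4.66 ± 0.267 against 0.601 ± 0.192 (1.83 ± 0.09, adjusted p = 1.14e-06). Nid2, a basement membrane protein, rose from 13.4 ± 3.63 to 46.0 ± 3.80 FPKM (adjusted p = 0.000262) and Col11a1, a fibrillar collagen, from 5.35 ± 0.704 to 16.3 ± 0.402 (adjusted p = 1.55e-06). Bmf, a pro-apoptotic member of the Bcl-2 family, rose 3.93-fold, the transcription factor Maf 3.14-fold and the small GTPase Rasl11b 3.97-fold in mean FPKM. Txnip, which restrains glucose uptake and thioredoxin, rose from 11.5 ± 5.23 to 34.5 ± 6.73 FPKM (adjusted p = 0.0148).

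The largest falls were in Prl2c3, a proliferin, from 47.9 ± 16.8 to 3.76 ± 1.22 FPKM (log2 change −3.33 ± 0.31, adjusted p = 0.000736), and in Ereg, a ligand of the epidermal growth factor receptor, from 31.2 ± 7.40 to 2.66 ± 0.0478 (−3.11 ± 0.15, adjusted p = 4.07e-06). Prl2c3 belongs to a family of near-identical genes, so its level is uncertain. Hmox1, which frees iron from heme, fell from 224 ± 29.5 to 28.8 ± 0.727 FPKM (−2.90 ± 0.09, adjusted p = 2.26e-07), and Ptgs2, the inducible cyclooxygenase, from 124 ± 18.7 to 24.5 ± 1.20 (−2.28 ± 0.10, adjusted p = 1.82e-06). Ier3 was 6.70-fold, Fos 9.06-fold, Id1 5.23-fold and the peptide hormone gene Cck 7.87-fold lower in mean FPKM. The Entrez identifiers are 67606 for Fibin, 12353 for Car6, 18074 for Nid2, 18812 for Prl2c3, 13874 for Ereg, 15368 for Hmox1 and 19225 for Ptgs2.

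**Figure D1:**
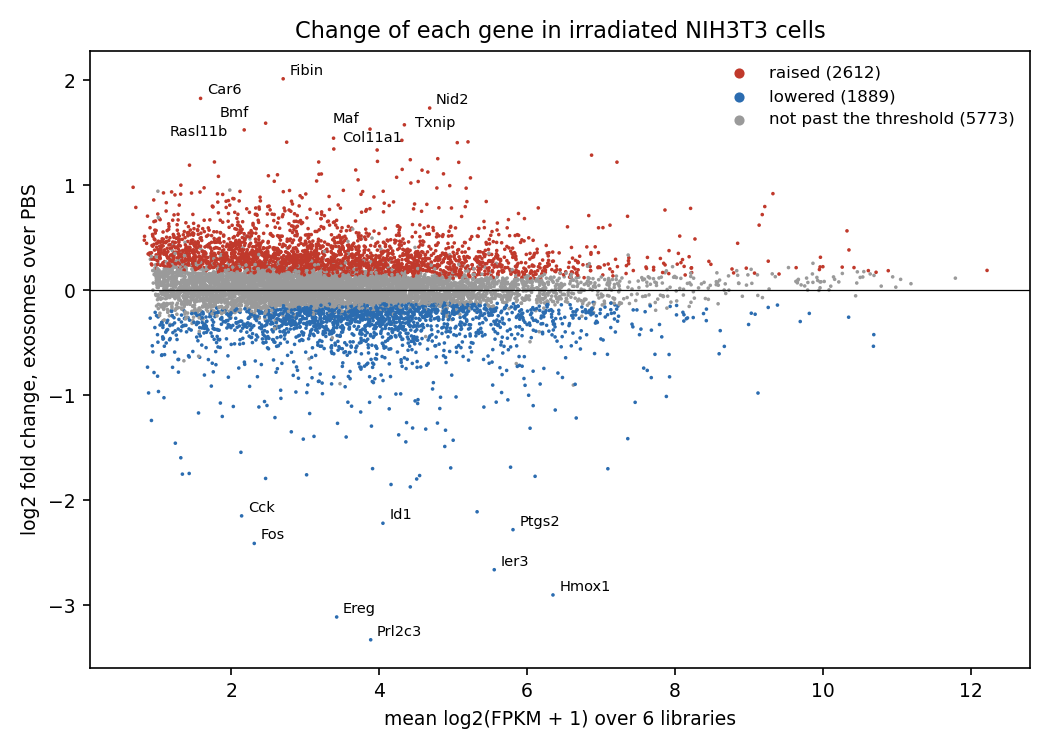
Log2 fold change of each tested gene (exosomes over PBS) against its mean log2(FPKM + 1) over 6 libraries. Red points are the 2612 raised genes, blue points the 1889 lowered genes and grey points the 5773 not past the threshold, and the 8 largest rises and 8 largest falls are named, from Fibin at 2.01 to Prl2c3 at −3.33.

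Among members past the threshold, more were lowered than raised with exosomes in both ferroptosis lists, promoting and restraining. Over all tested members, called or not, 11 changes were above 0 and 10 below in the promoting list. In the restraining list they were 6 and 21. In the list of ferroptosis-promoting genes 9 of 21 tested members fell, 3 rose and 9 did not pass (9 lowered and 3 raised when adjusted over the list alone). Those with the smallest p were Hmox1, Ptgs2 and Tfrc, the transferrin receptor that imports iron, which fell from 22.4 ± 1.79 to 8.52 ± 0.418 FPKM (log2 change −1.29 ± 0.06, adjusted p = 1.18e-06). Acsl4, which activates polyunsaturated fatty acids, fell from 28.5 ± 3.45 to 22.2 ± 1.69 FPKM (adjusted p = 0.0123), and Ncoa4, the receptor for ferritin breakdown, rose from 7.86 ± 0.185 to 9.16 ± 0.339 (adjusted p = 0.0122), a call lost without PBS replicate 1 (adjusted p = 0.0505). Hmox1 is also an antioxidant gene, and Ptgs2 is used mainly as a marker. Camera gave an adjusted p of 0.0262 for a fall of this list, and 0.164 with an estimated correlation. The call also ended without the filter on low values (0.0717) and with at least 5 FPKM (0.0553), and the list's median change of 0.02 differs in sign from its mean of −0.36.

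In the list of ferroptosis-restraining genes 17 of 27 tested members fell, 3 rose and 7 did not pass, with 17 lowered and 4 raised when adjusted over the list alone. Gclc and Gclm, the subunits of the enzyme that starts glutathione synthesis, fell from 18.1 ± 0.722 to 6.24 ± 0.243 FPKM (log2 change −1.40 ± 0.05, adjusted p = 3.98e-07) and from 39.5 ± 1.54 to 19.0 ± 0.480 (−1.02 ± 0.05, adjusted p = 7.57e-07). Srxn1, sulfiredoxin, fell from 57.5 ± 2.92 to 35.4 ± 1.37 FPKM (adjusted p = 1.21e-05). Slc7a11, the cystine importer, was 1.39 ± 0.0925 FPKM with exosomes and 2.73 ± 0.368 with PBS (adjusted p = 0.000342), and the ferritin heavy chain gene Fth1 was 1366 ± 55.3 against 1978 ± 42.1 (adjusted p = 7.84e-05). Gpx4, the enzyme that reduces lipid hydroperoxides, went the other way, from 109 ± 4.84 to 141 ± 15.2 FPKM (log2 change 0.36 ± 0.07, adjusted p = 0.00386). For a fall of the list camera gave an adjusted p of 5.79e-07, and 0.063 with an estimated correlation. Of the 27 members 8 also belong to the NRF2 antioxidant list, and of the other 19 members 9 fell and 3 rose. Fth1 and Gpx4 have processed pseudogenes that can share their reads, so their levels are uncertain.

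DNA replication genes fell with exosomes, and most mitosis genes did not pass the test. Of 30 replication genes 23 were lowered, 0 raised and 7 not past the threshold (25 lowered when adjusted over the list alone), with a median log2 change of −0.34. Cdt1, which licenses replication origins, fell from 17.3 ± 1.23 to 10.3 ± 1.09 FPKM (log2 change −0.70 ± 0.08, adjusted p = 0.000129), Mcm3 of the replicative helicase from 24.1 ± 1.26 to 16.7 ± 0.845 (adjusted p = 0.000145) and the flap endonuclease Fen1 from 14.7 ± 1.07 to 9.82 ± 0.671 (adjusted p = 0.000262). Pcna, the polymerase clamp, fell from 65.4 ± 5.46 to 44.6 ± 3.73 FPKM (−0.54 ± 0.07, adjusted p = 0.000452). Camera gave an adjusted p of 2.43e-09 for the replication list, and 0.273 with an estimated correlation. The G1 cyclin gene Ccnd1 was 32.2 ± 3.01 against 41.6 ± 2.10 FPKM (adjusted p = 0.00252).

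Among 30 mitosis genes 3 fell, 0 rose and 27 did not pass, and 0 passed when adjusted over the list alone (median log2 change −0.02, camera adjusted p = 0.134). Without PBS replicate 3 the mitosis list was called lower (camera adjusted p = 0.0096). The 3 were Cdk1, 16.8 ± 0.288 against 19.5 ± 1.21 FPKM (adjusted p = 0.0141), Foxm1, 9.97 ± 0.486 against 12.1 ± 1.19 (adjusted p = 0.0148), and Aurkb, 4.30 ± 0.385 against 5.40 ± 0.609 (adjusted p = 0.0248). Without PBS replicate 1 all 3 calls ended (adjusted p = 0.0615, 0.0534 and 0.095), and without exosome replicate 1 those of Foxm1 (0.059) and Aurkb (0.0923) did. The Aurkb call also ended without the filter on low values (0.0616). Mki67, a marker of cycling cells, was 7.77 ± 1.09 with exosomes and 9.20 ± 1.01 with PBS (adjusted p = 0.107, and 0.0386 without PBS replicate 3). Ccnb1, the mitotic cyclin B1, was 12.9 ± 1.05 against 12.9 ± 1.45 FPKM, a log2 change of 0.01 ± 0.08 (adjusted p = 0.96).

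**Figure D2:**
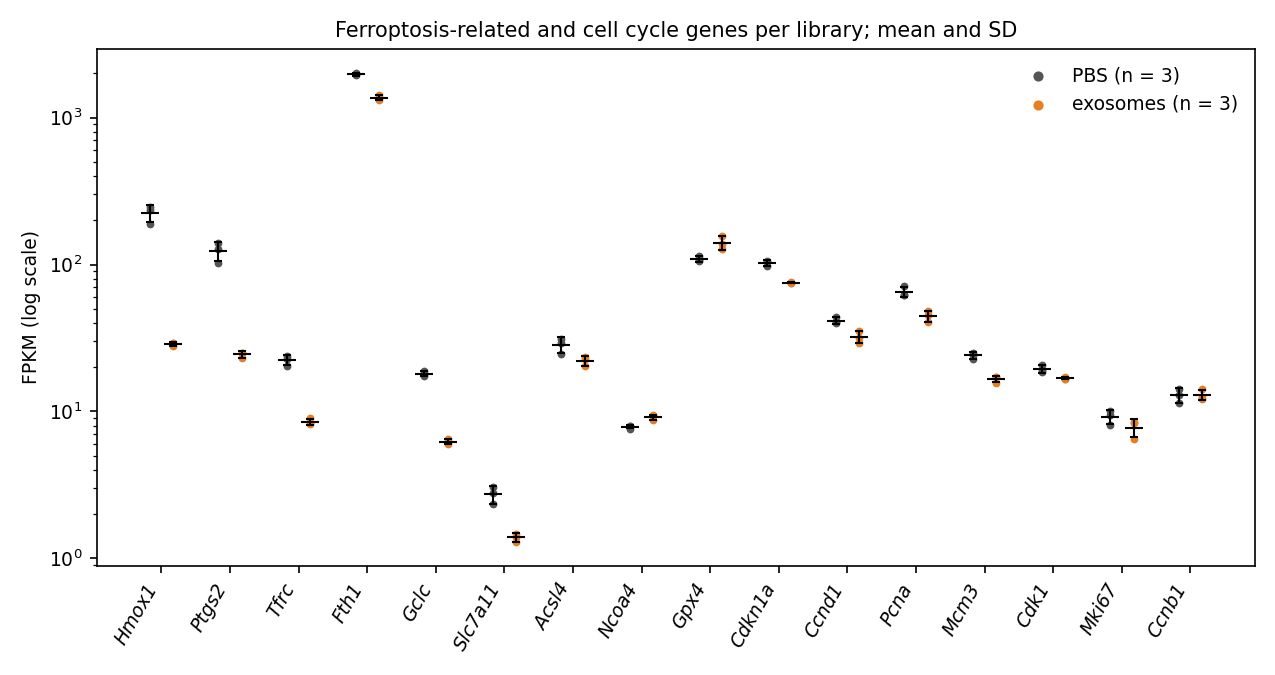
FPKM of 16 ferroptosis-related and cell cycle genes in each library on a log scale, with grey points for 3 PBS and orange points for 3 exosome libraries, and black marks for the mean and SD. Hmox1 lies at 28.8 FPKM with exosomes and 224 with PBS, Pcna at 44.6 and 65.4, Gpx4 at 141 and 109, and Ccnb1 at 12.9 and 12.9.

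Immediate early genes, which growth factors and stress induce within minutes to hours, showed the lowest list median, −1.03. Of 30 members 25 fell, 1 rose and 4 did not pass, with the same counts when adjusted over the list alone. Fos fell from 10.5 ± 0.588 to 1.16 ± 0.154 FPKM (log2 change −2.41 ± 0.07, adjusted p = 1.85e-07), Maff from 13.9 ± 0.926 to 3.41 ± 0.141 (−1.76 ± 0.06, adjusted p = 2.26e-07) and Fosl1 from 55.4 ± 4.78 to 16.4 ± 1.35 (−1.69 ± 0.07, adjusted p = 6.90e-07). The member that rose was Jund, an AP-1 subunit (0.38 ± 0.07, adjusted p = 0.00249). Genes of glycolysis and the hypoxia response fell as well: 24 of 27 members were lowered, 0 raised and 3 not past the threshold (25 lowered over the list alone), with a median of −0.70. Hk2, hexokinase 2, went from 26.2 ± 1.47 to 7.35 ± 0.0298 FPKM (−1.70 ± 0.05, adjusted p = 1.85e-07), Ldha, lactate dehydrogenase A, from 335 ± 7.63 to 165 ± 3.07 (adjusted p = 6.90e-07) and the glucose transporter gene Slc2a1 from 123 ± 4.97 to 55.2 ± 2.89 (adjusted p = 6.90e-07). Gapdh was listed at only 2.57 ± 0.140 and 4.74 ± 0.156 FPKM, and its value is uncertain because many pseudogenes can share its reads, which was not tested. These were the 2 lists whose camera call held with an estimated correlation (adjusted p = 0.0127 for each, against 6.19e-18 and 3.44e-19 with the preset value).

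The antioxidant targets of the transcription factor NRF2 fell in 24 of 26 members, with 0 raised and 2 not past the threshold (24 lowered and 1 raised over the list alone), and a median of −0.49. Hmox1, Gclc and Gclm had the smallest p, and Nqo1, a quinone reductase, fell from 46.6 ± 5.58 to 17.9 ± 2.84 FPKM (log2 change −1.33 ± 0.12, adjusted p = 8.27e-05). For this list camera gave an adjusted p of 6.34e-14, and 0.0575 with an estimated correlation.

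Secreted factors linked to senescence fell in 12 of 18 members, with 1 raised and 5 not past the threshold (14 and 1 over the list alone), and a median of −0.69. The chemokine gene Cxcl1 fell from 40.2 ± 4.86 to 10.2 ± 0.545 FPKM (log2 change −1.87 ± 0.08, adjusted p = 8.16e-07) and the urokinase receptor gene Plaur from 33.6 ± 2.56 to 12.9 ± 0.657 (adjusted p = 1.03e-06). Igfbp4, which binds insulin-like growth factors, was the member that rose (1.11 ± 0.08, adjusted p = 1.75e-05). Il6 was 0.891 ± 0.242 against 1.24 ± 0.298 FPKM (adjusted p = 0.126, and 0.0423 without PBS replicate 2). The camera adjusted p of the list was 1.68e-08, and 0.164 with an estimated correlation. NF-kB targets fell in 11 of 20 members, with 0 raised and 9 not past the threshold, both over all genes and over the list alone (camera adjusted p = 2.36e-06, and 0.0586 with an estimated correlation). The members of smallest p were Ier3, Cxcl1 and the prostaglandin E synthase gene Ptges, which fell from 31.0 ± 1.31 to 18.5 ± 0.492 FPKM (adjusted p = 6.95e-06). The list median was −0.34. Of these 20 members 5 are also in the senescence list, and of the other 15 members 7 fell and 0 rose, with a median of −0.12. Leukocyte markers, summed, were at 0.71 ± 0.10 FPKM with exosomes and 2.36 ± 1.15 with PBS, Csf1r alone at 0.295 ± 0.0752 and 1.92 ± 1.24.

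Interferon response genes rose in 15 of 17 members, with 0 lowered and 2 not past the threshold, both over all genes and over the list alone, and a median log2 change of 0.58. Stat2, which carries the type I interferon signal, rose from 7.24 ± 0.262 to 13.5 ± 1.00 FPKM (log2 change 0.81 ± 0.06, adjusted p = 1.21e-05), Ifit1, an RNA-binding antiviral protein, from 0.792 ± 0.0566 to 3.12 ± 0.617 (adjusted p = 2.86e-05) and Ddx58, the RNA sensor RIG-I, from 4.90 ± 0.246 to 7.80 ± 0.321 (adjusted p = 7.75e-05). The camera adjusted p was 2.09e-06, and 0.224 with an estimated correlation.

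Extracellular matrix genes rose in 21 of 29 members, while 4 fell and 4 did not pass (22 and 4 over the list alone), with a median of 0.38. Lox, which cross-links collagen, rose from 466 ± 34.9 to 881 ± 6.47 FPKM (log2 change 0.92 ± 0.06, adjusted p = 5.49e-06), Col1a1 from 450.0 ± 22.7 to 782 ± 16.5 (0.80 ± 0.05, adjusted p = 5.85e-06) and Col5a2 from 88.3 ± 5.50 to 145 ± 2.14 (adjusted p = 9.49e-06). Tnc, Col8a1, Fn1 and Bgn were the members that fell, Tnc by 0.72 and Fn1 by 0.30 on the log2 scale. By camera the matrix list had an adjusted p of 2.57e-05, and 0.226 with an estimated correlation. Genes of contraction and the TGF-beta response fell in 13 of 28 members, while 4 rose and 11 did not pass (14 and 4 over the list alone, camera adjusted p = 0.000191, and 0.297 with an estimated correlation). The matricellular gene Cyr61 fell from 127 ± 10.9 to 36.4 ± 3.04 FPKM (adjusted p = 6.90e-07), and Tgfbi rose from 5.21 ± 0.146 to 12.4 ± 0.139 (adjusted p = 6.90e-07). Acta2, smooth muscle actin, was 142 ± 9.27 with exosomes and 134 ± 18.7 with PBS (adjusted p = 0.456, and 0.0263 without PBS replicate 3). Of 20 angiogenic factors 7 fell, 5 rose and 8 did not pass (8 and 5 over the list alone, camera adjusted p = 0.0596, but 0.0398 for a fall with upper quartile scaling and 0.0307 without PBS replicate 2). Vegfa fell from 28.9 ± 1.18 to 20.9 ± 1.74 FPKM (adjusted p = 0.000474).

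Of 26 p53 targets 9 fell, 4 rose and 13 did not pass (9 and 6 over the list alone, camera adjusted p = 0.113, but 0.0414 for a fall without the filter on low values). Cdkn1a, which encodes the cell cycle inhibitor p21, was 75.3 ± 0.661 against 103 ± 4.33 FPKM (log2 change −0.44 ± 0.04, adjusted p = 7.90e-05), and Mdm2, the ubiquitin ligase of p53, 11.3 ± 0.561 against 15.1 ± 0.368 (adjusted p = 0.000394), whereas Gadd45a and Ddb2 rose by 0.67 and 0.49 on the log2 scale. DNA repair genes moved in both directions, with 7 of 28 lowered, 4 raised and 17 not past the threshold (the same counts over the list alone, camera adjusted p = 0.0689, but 0.046 for a fall without exosome replicate 2).

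Cholesterol synthesis genes rose in 15 of 29 members, with 1 lowered and 13 not past the threshold (16 and 1 over the list alone). Tm7sf2, a sterol reductase, went from 22.0 ± 0.633 to 31.8 ± 1.86 FPKM (adjusted p = 0.0001), Hmgcs1 from 102 ± 3.46 to 130.2 ± 0.943 (adjusted p = 0.000268) and Mvd from 38.8 ± 1.73 to 53.9 ± 4.90 (adjusted p = 0.000538). The camera adjusted p was 0.00383, and 0.456 with an estimated correlation. Of 30 oxidative phosphorylation genes 10 rose, 1 fell and 19 did not pass (the same counts over the list alone, camera adjusted p = 0.0596). The list was called higher without the filter on low values (0.0414), with upper quartile scaling (0.0363), with at least 5 FPKM (0.0347) and without exosome replicate 2 (0.00458). Of 30 ATF4 and unfolded protein response genes 11 rose, 9 fell and 10 did not pass (11 and 10 over the list alone, camera adjusted p = 0.646).

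Cytosolic ribosomal protein genes rose in 7 of 30 members, 0 fell and 23 did not pass, and 1 rose when adjusted over the list alone. Among all 10274 tested genes 2612 were raised, a slightly larger share. Rpl3 went from 248 ± 15.8 to 303 ± 17 FPKM (adjusted p = 0.00433), Rpl4 from 924 ± 55.4 to 1077 ± 53.5 (adjusted p = 0.0161) and Rpl10a from 277 ± 20.1 to 320.2 ± 18.4 (adjusted p = 0.025), with reads that pseudogenes can share. The camera adjusted p was 0.012, and 0.625 with an estimated correlation, and the call ended without exosome replicate 3 (0.0665) and without PBS replicate 3 (0.0526). Fry, which does not compare the list with other genes, gave it an adjusted p of 0.103. The Rpl4 call ended without exosome replicate 3 (0.0538), PBS replicate 1 (0.0665) or PBS replicate 3 (0.0514), and the Rpl10a call without exosome replicate 1 (0.0943) or 3 (0.0746) or PBS replicate 1 (0.083) or 3 (0.0757), or without the filter on low values (0.06). Of 30 replication-dependent histone genes 3 could be tested, of which Hist1h1c rose (0.39 ± 0.08, adjusted p = 0.00439) and 2 did not pass.

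**Figure D3:**
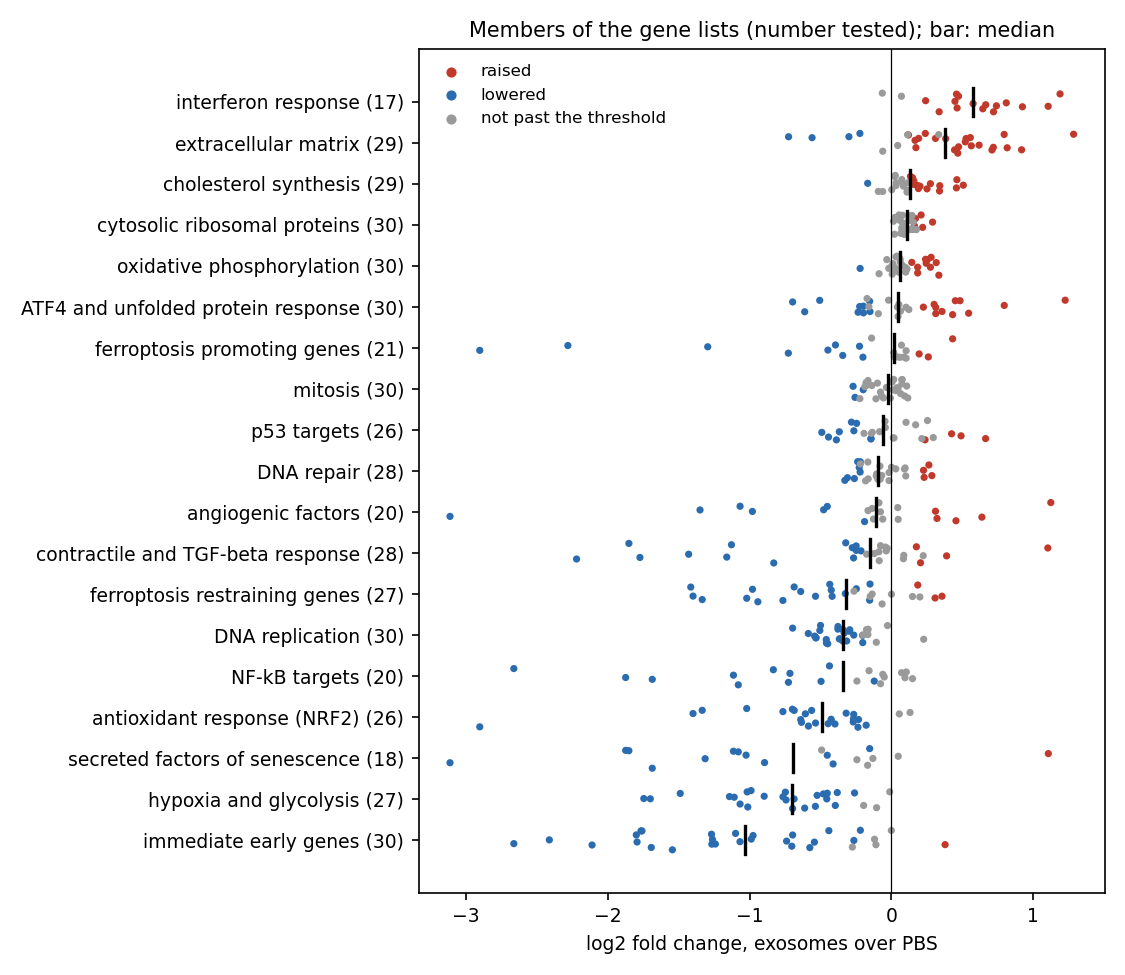
Log2 fold change (exosomes over PBS) of each tested member of the 19 gene lists with a set test, with red points raised, blue points lowered, grey points not past the threshold and a black bar at the list's median. Medians run from −1.03 for immediate early genes to 0.58 for interferon response genes.

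Summed markers of other cell types were highest for adipocytes and next for platelets. For the remaining cell types the group means were at most 4.40 FPKM. Their summed FPKM were 1.58 ± 0.67 with exosomes and 1.30 ± 0.36 with PBS for 9 erythroid markers, 0.71 ± 0.10 and 2.36 ± 1.15 for 16 leukocyte markers, and 10.59 ± 1.63 and 8.38 ± 1.15 for 12 platelet markers. For 14 markers each they were 0.29 ± 0.06 and 0.33 ± 0.12 for hepatocytes, 4.40 ± 0.72 and 3.73 ± 0.32 for endothelial cells, 1.33 ± 0.13 and 1.57 ± 0.10 for keratinocytes, 2.80 ± 0.10 and 2.35 ± 0.51 for skeletal muscle, and 46.6 ± 0.74 and 26.56 ± 1.09 for adipocytes. The most abundant adipocyte marker, the lipoprotein lipase gene Lpl, rose from 21.0 ± 2.28 to 42.8 ± 0.172 FPKM (limma adjusted p = 7.24e-06), while Fabp4 fell by 0.78 on the log2 scale and the third tested member did not pass. The most abundant leukocyte marker was Csf1r, the receptor of a macrophage growth factor, at 0.295 ± 0.0752 FPKM with exosomes and 1.92 ± 1.24 with PBS, too low for the test here, and the authors' deposited table gives it a log2 fold of −2.82 (adjusted p = 0.039). Without the filter on low values 11 leukocyte markers were tested as a list (camera adjusted p = 0.361). Hbb-bs of the erythroid list was at 0.694 ± 0.484 against 0.652 ± 0.295 FPKM, Serpina1a of hepatocytes at 0.187 ± 0.108 against 0.204 ± 0.0746 and Sfn of keratinocytes at 0.508 ± 0.148 against 0.455 ± 0.0671. Gp1bb of platelets was at 6.18 ± 1.27 against 4.57 ± 0.971 FPKM (adjusted p = 0.096, but 0.0166 without exosome replicate 3 and 0.0391 without PBS replicate 3), and Egfl7 of endothelial cells at 2.60 ± 0.689 against 1.81 ± 0.280 (adjusted p = 0.0727, but 0.00657 without exosome replicate 2). Actc1 of skeletal muscle was at 1.44 ± 0.0766 against 1.43 ± 0.269 (adjusted p = 0.929). Itga2b, the other platelet marker tested, rose (0.40 ± 0.10, adjusted p = 0.00862).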

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

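Median-of-ratios and upper quartile scaling, the 5 FPKM filter and treat were chosen after seeing the data. With a pseudocount of 0.1, 4495 genes passed, without the filter on low values 4312, with median-of-ratios scaling 4519, with upper quartile scaling 4614 and with at least 5 FPKM 3430. Scaling moved the share of raised genes among the calls from 58% to 51% (median of ratios) or 63.2% (upper quartile), and the median log2 change of all genes from 0.036 to 0.009 or 0.055. Leaving out each library in turn gave 3417 to 4433 genes, 2032 to 2619 raised and 1371 to 1814 lowered, and 12 to 15 gene lists. Of the 4501 calls, 0 had the opposite sign in any of these settings that tested them. A minimum absolute log2 change of 1 left 116 genes (41 raised, 75 lowered), and treat against 0.5 left 185 (75 raised, 110 lowered), since both add a bound on size to the same test. With an estimated inter-gene correlation camera called 2 lists in place of 13, with estimates from −0.03 to 0.721. The hypoxia and glycolysis list had an estimate of 0.024, near the preset 0.01, yet its camera adjusted p went from 3.44e-19 to 0.0127. This argues against the size of the estimate as the whole cause. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries, and with a preset one from the genes. Fewer degrees of freedom raise p, so a call lost with the estimate need not reflect correlation between genes. Fry called 14 lists and, for change in either direction, 17. Its 14 lists held DNA replication (fry adjusted p = 0.0118), matrix (0.00102), interferon (0.00176) and NRF2 genes (5.54e-05), but not ribosomal protein genes (0.103). With the replicate block 3914 genes passed (2288 raised, 1626 lowered), 3849 of them among the 4501, and 13 lists. The block ended the calls of Txnip (adjusted p = 0.0552), Aurkb (0.0527), Rpl4 (0.065) and Rpl10a (0.0659). Deviations of equally numbered libraries correlated at −0.12, −0.021 and −0.295 across genes, and no library correlated best with its own number. These values gave no sign of pairing by number, but they cannot show whether equally numbered libraries shared a culture. Over all alternatives, 761 results of named genes kept their direction and side of the threshold, 19 dropped out of it, 7 passed newly and 0 turned. Without the filter the calls of Aurkb (0.0616) and Rpl10a (0.06) ended, and the cause was not tested. DESeq2 size factors, upper quartile factors in edgeR, the filter of 50 counts, the DESeq2 Wald test, limma-voom and glmTreat need counts per library and were not run. At the estimated 18800000 to 22000000 counted reads and 3 libraries per group, log2 changes of 0.25 were recovered in 38.8% of simulated genes. Only 200 of 10274 genes were changed in each simulated draw. The 4501 calls here loosen the adjusted threshold, so that rate does not carry over to these data. A gene not called here can still differ by that much.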

Other observations

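The enrichment, blood cell and regrouping tests and the test of fewer cycling cells were chosen after the results were seen, and the bounds of the blood cell and cycling cell tests were set again after a first version. The trend, MAPK and FOXO tests were fixed before their results were seen. Bootstrap intervals are over genes, which are not independent.

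Among annotated terms, genes for burning branched-chain amino acids and fatty acids and genes of the primary cilium were over-represented among the raised genes. Of 41 tested genes of valine, leucine and isoleucine degradation 27 were raised and 0 lowered (9.8 raised by chance, adjusted p = 3.71e-06), among them Acadm, medium-chain acyl-CoA dehydrogenase, at 39.2 ± 1.04 FPKM with exosomes and 25.7 ± 2.02 with PBS (n = 3 each, limma adjusted p = 7.16e-05), and Aldh6a1, at 10.7 ± 0.396 against 6.77 ± 0.342 (adjusted p = 5.26e-05). Of 32 genes of fatty acid degradation 19 were raised and 4 lowered (adjusted p = 0.00261), but among the 17 outside the first term 7 and 4, and of 62 peroxisome genes 29 and 7 (adjusted p = 0.00614). Of 139 cilium assembly genes 66 were raised (35.3 by chance, adjusted p = 1.63e-05), and of 25 genes of transport within the cilium 16 were raised and 0 lowered (adjusted p = 0.00912), with Ift81 at 12.9 ± 0.361 against 8.91 ± 0.202 FPKM (adjusted p = 7.09e-05). The transport term shares 17 genes, 12 of them raised, with cilium assembly, and of its other 8 genes 4 were raised. Of 54 genes of smoothened signalling, the hedgehog pathway that runs through the cilium, 32 were raised and 6 lowered (adjusted p = 0.000109), but 23 of the 32 are also cilium assembly or transport genes, and of the 23 members outside those terms 9 were raised and 6 lowered. Gli2 rose (0.36 ± 0.06, adjusted p = 0.00102), Gli3 (−0.22 ± 0.05, adjusted p = 0.00721) and Hes1 (−1.17 ± 0.12, adjusted p = 0.000103) fell on the log2 scale, and Ptch1 (0.16 ± 0.08, adjusted p = 0.134) and Smo (0.07 ± 0.06, adjusted p = 0.416) did not pass. KEGG terms numbered 284 and GO terms 2440, the tests treat genes as independent, and these named genes were chosen after their values were seen.

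Among the lowered genes stood those that build ribosomes and nuclear pores. Of 68 tested genes of ribosome biogenesis 32 were lowered and 1 raised (14.8 lowered by chance, adjusted p = 0.000807), with the nucleolar genes Gnl3 at 24.3 ± 0.951 against 37.0 ± 2.07 FPKM (adjusted p = 4.59e-05) and Fbl at 63.4 ± 2.11 against 84.1 ± 1.36 (adjusted p = 0.00011), while genes of the finished ribosome's proteins had a median log2 change of 0.11. Of 58 nuclear pore genes 25 were lowered and 2 raised (adjusted p = 0.00156). Of 35 genes of the KEGG ferroptosis term 16 were lowered and 7 raised (7.6 lowered by chance, adjusted p = 0.0319). Most of these 16, among them Hmox1, Gclc, Gclm and Tfrc, also belong to the ferroptosis lists above, so the term is not independent of them. It holds promoting and restraining genes together. Of the ATF4 and unfolded protein response list, in which 11 members rose and 9 fell, Trib3 (1.23 ± 0.15), Pycr1 (0.80 ± 0.08), Slc7a5 (0.49 ± 0.07) and Asns (0.36 ± 0.04) rose on the log2 scale and Dnajb9 (−0.61 ± 0.07), Hsp90b1 (−0.23 ± 0.05) and Calr (−0.22 ± 0.06) fell, named here after their values were seen.

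Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave 4501 genes, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached. Culture, plate and harvest day are not in the labels, so an effect of these on any pattern below was not tested and stays open.

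Immediate early, glycolytic and NRF2 genes fell together, though the NRF2 call was lost with an estimated correlation (adjusted p = 0.0575). Removing the trend of the log2 change with transcript length and abundance left list medians of −0.55 or lower, which argues against that trend as the whole cause. A hypothesis is that growth factor signalling was weaker at 72 h after exosomes, which may lower these genes together. Among 11 further MAPK output genes 7 were lowered and 1 raised, with a median of −0.35 (95% bootstrap interval −1.0 to 0.02), and among 15 further FOXO targets, which rise when such signalling falls, 7 were raised and 2 lowered, with a median of 0.17 (−0.06 to 0.46). Both medians lie on the side the hypothesis needs, both intervals include 0, and the hypothesis stays open.

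Interferon response genes rose, a call of the list that was lost with an estimated correlation (adjusted p = 0.224). After removal of the length and abundance trend their median was 0.53 (95% bootstrap interval 0.30 to 0.67), outside the range within 0.1 of 0 that such a trend would need as the whole cause, although the interval touches the stricter bound of 0.3 set beforehand. RNA of mouse leukocytes or red cells carried over with the plasma would bring their abundant transcripts, but the 16 leukocyte markers summed to 0.71 FPKM in the exosome libraries and 2.36 with PBS and the 9 erythroid markers to 1.58 and 1.30, against a rise of 7.37 FPKM (SD 2.15) in Isg15 alone, which argues against both. The platelet markers were together higher with exosomes by 2.21 FPKM (SD 2.0), less than the rise of Isg15, but Itga2b was raised (adjusted p = 0.00862) and their level was not low in either group (10.59 and 8.38 FPKM), so RNA of platelets stays open, as does plasma of another species, which was not tested. That the exosome preparation may itself have triggered an interferon response in the fibroblasts stays a hypothesis that these libraries did not test.

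Replication genes fell without a like fall of mitosis genes, although the replication call was lost with an estimated correlation (adjusted p = 0.273) and the mitosis list was also called lower without PBS replicate 3 (camera adjusted p = 0.0096). The same contrast, already seen when this test was written, was put per library: mean log2(FPKM + 1) of replication minus mitosis genes was −0.03 ± 0.03 with exosomes and 0.25 ± 0.04 with PBS (SD, n = 3), a difference of −0.28 that ran from −0.30 to −0.26 with each library left out, which argues against a smaller share of cycling cells in every phase as the whole cause. After removal of the length and abundance trend the replication median minus the mitosis median was −0.31 (95% bootstrap interval −0.41 to −0.22), which argues against that trend. Means of replication genes were 3.05 to 3.21 with exosomes and 3.38 to 3.56 with PBS, and of mitosis genes 3.06 to 3.23 and 3.08 to 3.34. A lower rate of entry into S phase, or a longer stay in G2 or mitosis, may give such values, and neither was tested.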
